A study of Homo sapiens with 29 samples.

How the data were processed

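RNA of human placenta was hybridised to 29 Affymetrix arrays with 54675 probe sets each. Per the labels, total RNA was labelled with biotin, and the samples are 10 VUE patients with a High and a Low array each and 9 controls. The deposited values are log2 signals per probe set, between 1.29 and 14.3. The submitters' processing notes name Partek and GCRMA, a background correction and normalization method that uses probe sequence, and their versions, settings and order are not given in the sources used here. The log base was read from the range of the values, since no file header states it. No array repeated another. Array medians lay between 5.11 and 5.40, and the values were not normalized further.

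Probe sets were named through an older platform annotation, and gene identifiers were checked against RefSeq names for assembly GRCh38.p14, whose coordinates were not used. Of the probe sets, 41091 had 1 gene symbol, 1801 several and 11721 none, and 62 were controls. Of those with 1 symbol 41037 matched by gene identifier, and 0 symbols changed. Probe sets of genes tied to sex, 106 in all, were removed before any test. Each gene was represented by its probe set with the highest mean over all arrays. This choice mattered for 10508 genes with several probe sets. For genes named in Results, the text says where probe sets differ in sign, and gives differences in size for some of these genes only. Probe sets of genes named only under Other observations are not compared. A probe set measures the transcripts that its probes match, so variants in the HLA genes can change binding between donors. Genes had to exceed a log2 value of 4 on at least 9 arrays. This left 17116 of 19733 genes. Of the fixed panel, HLA-A and STAT1 were not analysed here.

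Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There were 4 comparisons, namely High against control, Low against control, the mean of both arrays of each patient against control, and High against Low with the patient as a block. The labels give both arrays of a patient the same number, so those pairs share a donor. Deviations from the group mean correlated at 0.11 to 0.93 within the 10 patients, over 0.1 in all of them. Comparisons that use the same controls are not independent of each other, and their gene lists were not compared. Donors are separate people, so the p-values of the comparisons with control measure the spread between donors. Those of High against Low measure how the differences within patients vary. Other traits of the donors were not used. Measures of whole arrays were compared with exact permutation tests, in 9 tests adjusted together. Differences between the means of 2 lists were compared between High and control arrays by permuting the residuals of the model without the group (100000 resamples, two-sided, 8 tests adjusted together). Values after ± are SD for group means and SE for differences.

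Before the data were examined, 25 gene lists were fixed for placental cell types, immune cells and interferon responses, along with the rule for named genes. It takes the 8 largest rises and falls past the threshold in High against control, Low against control and High against Low, a fixed panel in every comparison, and, for lists described, up to 4 members with the smallest p. The lists whose members are named were picked after their values were seen. Lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. For each list the text counts members past the threshold over all genes and adjusted over the list alone.

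The alternatives fixed before the data were examined were other filters, other ways to join probe sets, median centring, quantile normalization, array weights, no variance trend, a limit of 1 on the log2 change, other blocks, all 29 arrays in 1 fit with the donor as a random block, and leaving out each donor. After the data were seen, array spread (the SD of all log2 values of an array) and the GAPDH 3' to 5' difference were tried as covariates, as was leaving out VUE patient 7 together with array spread, and list members were counted with each donor left out.

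The code was tested on simulated data with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale among 17116. In the simulation of High against control, 37.3%, 83.6% and 100% of these were found, with 6.37% of the calls false. For Low against control the shares were 25.4%, 86.6% and 100%. For the patient means they were 50.7%, 91.0% and 100%, and for High against Low 71.6%, 98.5% and 100%. False calls made up 6.62% for Low against control, 5.29% for the patient means and 8.63% for High against Low. An HLA class II list shifted by 1 was called in each of the 4 simulated comparisons. At the preset correlation 1 other list, which was not shifted, was also called for the patient means. Noise was drawn for each gene apart from the others, and the simulations were not repeated. In the measured data genes varied together, with an estimated correlation of 0.4 for the class II list in High against control. The simulated shares and list calls thus test the code and may not hold for these data.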

Results

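Gene expression was measured in human placenta on 29 microarrays from 19 donors. Villitis of unknown etiology (VUE) is an inflammatory lesion of the chorionic villi, the fetal part of the placenta that takes up nutrients, in which T cells and macrophages enter villi without a known infection. The VUE samples came from 10 patients, each with an array labelled High and an array labelled Low, and the other 9 arrays were controls. What High and Low stand for is not given in the sources used here, and the names are used as labels only. Each value was a log2 signal of a probe set, and 17116 genes were tested. HLA-A and STAT1, fixed for naming in every comparison, were not analysed here. Array medians lay between 5.11 and 5.40, and the number of donors limits the precision of every comparison.

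The comparison of High arrays with controls asked how VUE tissue with the label High differed from control placenta. The largest rises were in CXCL10 and CXCL9, chemokines induced by interferon gamma that attract T cells. CXCL10 averaged 10.02 ± 0.93 (SD, n = 10) on High arrays and 5.52 ± 0.63 (SD, n = 9) on control arrays, a difference of 4.50 ± 0.33 (SE; limma, adjusted p = 7.3e-08). CXCL9 averaged 10.17 ± 1.07 (SD, n = 10) against 5.79 ± 0.91 (SD, n = 9), a difference of 4.38 ± 0.41 (SE; limma, adjusted p = 3.04e-06). Both genes lay above the control mean on 10 of 10 High arrays. SLAMF7, a receptor of activated lymphocytes and plasma cells, rose by 4.13 ± 0.42 (SE), though its probe sets ranged from 0.53 to 4.13. The other genes among the 8 largest rises were HLA-DPA1 at 3.00, the immunoglobulin light chain gene IGLC1 at 2.99, ANKRD22 at 2.70, HLA-DQA1 at 2.38 and the protease inhibitor SERPINA1 at 2.16. The probe sets of IGLC1 ranged from 0.03 to 2.99 and those of SERPINA1 from 0.19 to 2.16. HLA-DQA1 had an SD of 2.48 on High arrays and lay above the control mean on 8 of 10, and with array spread (the SD of all log2 values on an array) in the model its difference of 2.38 ± 0.87 became 3.01 ± 1.10 and its adjusted p of 0.0383 became 0.134.

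HLA class II genes, which present peptides to helper T cells, rose as a group in High arrays. All 13 measured members passed the threshold over all genes, and the same 13 passed when adjusted over the list alone, with a median difference of 1.29. CD74, the chaperone of class II molecules, rose by 2.11 ± 0.22 (SE; adjusted p = 6.19e-06), HLA-DRA by 2.05 ± 0.48 and CIITA, the master regulator of class II transcription, by 1.30 ± 0.21. The list was called by camera with a preset correlation (adjusted p = 8.75e-08), and not with one estimated from the data (adjusted p = 0.194 with an estimated correlation). The median of the list was 1.96 with array spread as a covariate, 11 of 13 genes passed, and adjusted p = 0.00506 with an estimated correlation.

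Genes that respond to interferon gamma also rose. Of 19 measured members, 13 rose, 1 fell and 5 did not pass; adjusted over the list alone, 15 rose and 1 fell. The median difference was 0.63 and the camera call (adjusted p = 9.79e-05) was lost at adjusted p = 0.351 with an estimated correlation. GBP5, an interferon-induced GTPase, rose by 0.94 ± 0.18 (SE). IDO1, a tryptophan-degrading enzyme, differed by -0.18 ± 0.22 and did not pass (adjusted p = 0.505). In the model with array spread 13 members were higher, and adjusted p = 0.0199 with an estimated correlation. Among HLA class I and antigen processing genes 8 of 15 rose, and 8 rose and 1 fell adjusted over the list alone. These included the peptide transporter gene TAP1 at 0.93 ± 0.18, HLA-F at 0.83 ± 0.19, HLA-B at 0.86 ± 0.22 and HLA-E at 0.79 ± 0.20. The class I list was not called (adjusted p = 0.0705), though it was when VUE patient 7 or 10 or control 2, 8 or 10 was left out, and it was called with array spread as a covariate, also with an estimated correlation (adjusted p = 0.0226). Of 23 type I interferon response genes, 10 rose and 1 fell, over all genes and adjusted over the list alone. IFI35 rose by 0.51 ± 0.12 and IFI6 fell by 0.95 ± 0.23, both interferon-induced genes, and the list was not called (adjusted p = 0.0574), except when VUE patient 7, 8 or 10 or control 1, 2, 8 or 10 was left out. Neither gene passed with array spread as a covariate (0.27 and -0.38, adjusted p = 0.213 and 0.301). The list was called in that model, where 8 members were higher and 0 lower (limma; adjusted p = 0.022 with an estimated correlation).

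Markers of T cells and of killing were higher, at signals near the array median. Their means on control arrays were 5.41 ± 0.18 and 4.82 ± 0.16 (SD), where the array median averaged 5.18. Of 20 T cell markers 14 rose and 6 did not pass, or 15 rose adjusted over the list alone, with a median of 0.48. TRBC1, a constant region of the T cell receptor, rose by 1.17 ± 0.13 (SE; adjusted p = 1.99e-05), CD8A, the coreceptor of cytotoxic T cells, by 0.92 ± 0.12, and CD3D by 0.88 ± 0.13. Of 14 cytotoxic granule and killer lectin genes 12 rose, by either adjustment including that over the list alone. The pore-forming protein gene PRF1 rose by 1.15 ± 0.14, NKG7 by 0.79 ± 0.14, GZMA by 1.14 ± 0.22 and GZMB by 0.72 ± 0.20. Of 22 chemokines and their receptors 14 rose, also when adjusted over the list alone, among them CCL5 by 1.54 ± 0.20 and CCL8 by 2.10 ± 0.32. Of 20 immune checkpoint and regulatory genes 14 rose, or 15 adjusted over the list alone. They included the activation marker TNFRSF9 at 1.51 ± 0.23 and the inhibitory receptor CTLA4 at 1.06 ± 0.19, while CD274, which encodes PD-L1, differed by 0.16 ± 0.13 and did not pass, with its other probe set at -0.20. Other probe sets of TNFRSF9, CTLA4 and CCL5 went down to 0.0557, 0.162 and 0.215. For each of these 4 lists, adjusted p = 0.194 with an estimated correlation. Once array spread was a covariate, 8 T cell, 4 cytotoxic, 6 chemokine and 4 checkpoint genes passed, and the medians went from 0.48 to 0.20, from 0.46 to 0.26, from 0.45 to 0.41 and from 0.43 to 0.21. In that model adjusted p = 0.0199 for T cell markers and adjusted p = 0.0292 for the other 3 lists, each with an estimated correlation. The High array of VUE patient 7 had the highest T cell mean of the High arrays. Without this patient and without the covariate, 12 T cell and 11 cytotoxic genes rose.

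B cell and plasma cell markers were higher in 8 of 11 cases, or 9 adjusted over the list alone, among them POU2AF1 at 0.79 ± 0.17 and the light chain gene IGKC at 0.55 ± 0.16. Of the 16 markers fixed for this list, CD19, MS4A1, CR2, TNFRSF17 and JCHAIN were not tested. The list's camera call was lost at adjusted p = 0.452 with an estimated correlation, and 0 members passed with array spread as a covariate (limma), against 8 without it, where the median turned from 0.38 to -0.03. POU2AF1 was then at 0.68 (adjusted p = 0.0644) and IGKC at 0.22 (adjusted p = 0.492). The count of 8 was 5 without VUE patient 1, 6, 7 or 8 or control 5, 4 without control 1 or 10 and 3 without control 2 or 8. Markers of macrophages and of Hofbauer cells, the macrophages of the villus, went both ways. Of 19, 5 rose and 3 fell, the same counts as adjusted over the list alone, and the list was not called (adjusted p = 0.845), with a median of 0.05 but a test direction below 0. In the model with array spread 5 rose, 0 fell (limma) and the median was 0.45, with adjusted p = 0.253 with an estimated correlation. The 5 rises were 2 without VUE patient 1, 2, 5, 6 or 9 or control 1, 2, 7 or 8 and 3 without control 3, 4, 5 or 10, and the median ran from -0.01 to 0.17 with each donor left out. TYROBP, a signalling adaptor of myeloid cells, rose by 0.47 ± 0.09 and FOLR2, a folate receptor of tissue macrophages, fell by 0.53 ± 0.13, or differed by -0.36 with array spread as a covariate (adjusted p = 0.191). The scavenger receptor gene CD163 fell by 0.82 ± 0.27 (adjusted p = 0.0226), with probe sets from -0.82 to 0.23 and a difference of -0.26 (adjusted p = 0.674) with array spread as a covariate, and LYVE1 differed by -0.01 ± 0.36.

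**Figure D1:**
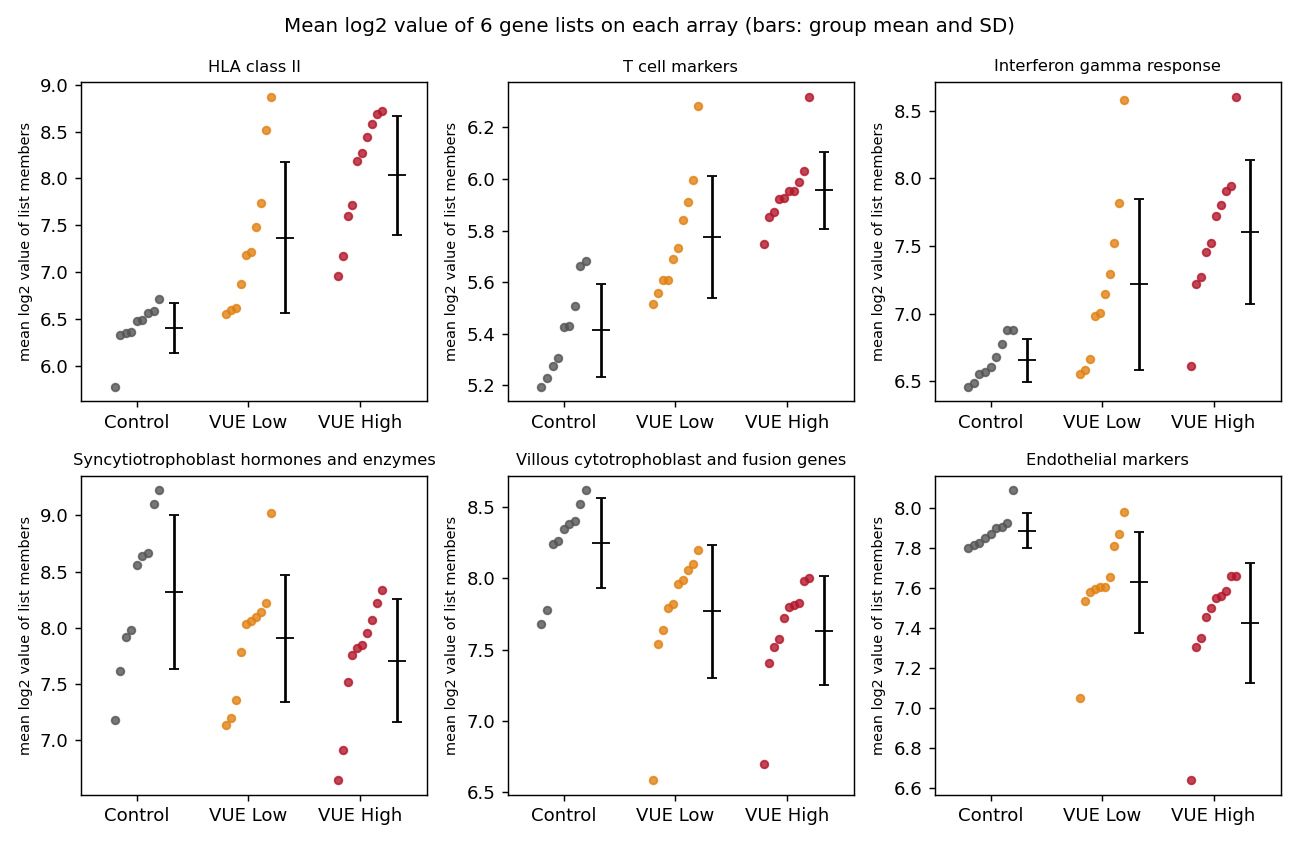
Mean log2 value of the measured members of 6 gene lists (y axis) on each array, by group (x axis), with 9 control, 10 VUE Low and 10 VUE High arrays. Points are arrays, sorted by value within a group, and bars give the group mean and SD. The HLA class II mean was 6.40 ± 0.27 in controls, 7.36 ± 0.81 in Low and 8.03 ± 0.63 in High arrays, and the endothelial mean was 7.89 ± 0.09, 7.63 ± 0.25 and 7.42 ± 0.30.

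Some genes of the trophoblast, the epithelium of the villus, fell in High arrays, while more members of its hormone and fusion lists did not pass. Of 25 genes for hormones and enzymes of the syncytiotrophoblast, the fused outer layer, 6 fell and 19 did not pass, or 5 fell adjusted over the list alone, with a median of -0.52, and 11 fell without control 2. CGA, the shared alpha subunit of glycoprotein hormones, fell by 1.30 ± 0.32 (SE; adjusted p = 0.00552), and differed by -0.99 with array spread as a covariate (adjusted p = 0.167). HSD3B1, an enzyme of progesterone synthesis, fell by 1.25 ± 0.31, with 1 of its 2 probe sets at 0.15. The placental lactogen gene CSH1 differed by -1.0 ± 0.47 and did not pass (adjusted p = 0.0868). Of 19 villous cytotrophoblast and fusion genes 9 fell, or 10 adjusted over the list alone. GCM1, a transcription factor that drives trophoblast fusion, fell by 2.04 ± 0.35 and TFAP2A by 1.01 ± 0.21. Of 16 solute transporters of the trophoblast 9 fell and 2 rose, by either adjustment including that over the list alone. With each donor left out, 0 to 2 rose and 8 to 9 fell. SLC2A1, the glucose transporter GLUT1, fell by 1.52 ± 0.23 (adjusted p = 0.000283) and FABP4, a fatty acid carrier, by 1.15 ± 0.23. With estimated correlations the adjusted p was 0.452 for the syncytiotrophoblast, 0.194 for the cytotrophoblast and 0.164 for the transporters. With array spread as a covariate 0 syncytiotrophoblast genes (limma), 1 cytotrophoblast gene and 1 transporter gene passed. The median then went from -0.52 to -0.81 for the syncytiotrophoblast, from -0.57 to -0.21 for the cytotrophoblast and from -0.46 to -0.26 for the transporters. In that model adjusted p = 0.292, 0.418 and 0.0292 with an estimated correlation, so the transporter list alone of these 3 was called. HSD3B1 (-0.94), TFAP2A (-0.52) and FABP4 (-0.77) did not pass in it either (adjusted p = 0.183, 0.14 and 0.0997).

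Of 16 endothelial markers 9 fell and 1 rose, or 10 fell and 2 rose adjusted over the list alone. SOX17, a transcription factor of arterial endothelium, fell by 1.19 ± 0.22 and the junction protein gene ESAM by 1.00 ± 0.21. Of 18 genes of villous stroma and matrix 5 fell and 1 rose, also adjusted over the list alone. The smooth muscle genes ACTA2 and MYH11 fell by 0.92 ± 0.25 and 0.73 ± 0.22, although 3 of 7 MYH11 probe sets had that sign. Of 16 immediate early and stress genes 7 fell and 1 rose by either adjustment, including that over the list alone. FOSB fell by 1.12 ± 0.22 and GADD45B by 0.84 ± 0.19, with 3 of 4 GADD45B probe sets of that sign. With estimated correlations the adjusted p of these lists was 0.194, 0.452 and 0.415, and with array spread as a covariate 0, 0 and 2 members were lower (limma). The medians of these lists went from -0.48 to -0.31, from -0.59 to 0.07 and from -0.26 to -0.15. Neither SOX17 (-0.77) and ESAM (-0.61) nor ACTA2 (-0.41), MYH11 (-0.34) and GADD45B (-0.71) passed in that model (adjusted p = 0.0597, 0.116, 0.403, 0.477 and 0.085). The stromal median was -0.34 without VUE patient 7, and 3 stromal genes fell without VUE patient 6 or control 2, 7 or 8, 8 without control 3. Without control 2, 4 stress genes fell. The 8 largest falls of all genes were led by SOX7, an endothelial transcription factor, at -2.74 ± 0.28 (SE; adjusted p = 6.19e-06). The others were TAC3 at -2.44, which encodes neurokinin B, APOLD1 at -2.41, DNAJB4 at -2.35, LYSMD3 at -2.32, NEXN at -2.31, the Wnt inhibitor DKK1 at -2.29 and ZNF512B at -2.25. The other probe set of DNAJB4 lay at -0.13 and that of ZNF512B at 0.05. TAC3 and DKK1 no longer passed with array spread as a covariate (-1.80 and -1.35, adjusted p = 0.0743 and 0.063). FLT1, a receptor for placental growth factor, differed by -0.39 ± 0.18 and did not pass, with probe sets from -1.41 to 0.15.

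Over all genes, 6389 of 17116 differed between High and control arrays (limma, adjusted p under 0.05), 3502 higher and 2887 lower. The balance turned under several alternatives, among them a stricter filter (1769 higher and 2250 lower) and array median centring (2929 and 3063). Of the 6389 genes, 788 differed by at least 1 on the log2 scale, 107 higher and 681 lower. The arrays themselves also differed between groups. The array median averaged 5.27 ± 0.055 on High, 5.26 ± 0.0517 on Low and 5.18 ± 0.0547 on control arrays (SD; exact permutation test, two-sided, p = 0.00331 for High and 0.0046 for Low against control, adjusted p = 0.0178 for both over 9 tests). Array spread averaged 1.67 ± 0.05 on High arrays, 1.68 ± 0.05 on Low arrays and 1.76 ± 0.06 on control arrays (exact permutation test, High against control p = 0.00592, adjusted p = 0.0178; Low against control p = 0.0127, adjusted p = 0.019). The difference between the 3' and 5' control probe sets of GAPDH, which can rise with RNA degradation, was -0.60 ± 0.51 on High arrays, -0.57 ± 0.58 on Low arrays and -1.09 ± 0.30 on control arrays (exact permutation test, p = 0.00915 for High and 0.0108 for Low against control, adjusted p = 0.019 for both). For the actin gene ACTB it was 3.70 ± 0.64, 3.78 ± 0.69 and 3.57 ± 0.33 (SD) and was not tested. Both arrays of VUE patient 7 had the highest values of all, 0.71 on High and 0.95 on Low for GAPDH and 5.34 and 5.60 for ACTB. The highest values on control arrays were -0.594 and 4.1. This patient stayed in the main comparisons, and these array tests were not repeated without it. Without patient 7, 5501 genes differed between High and control arrays, 2730 higher and 2771 lower. Whether RNA degradation differed between the groups, or in this patient only, is thus not settled. With array spread as a covariate 735 genes differed, of which 544 were among the 6389 and had the same direction. Array spread is a summary of the same values, so this model can also remove a difference that belongs to the groups, or create or enlarge one. Lists called only with this covariate carry that limit. Without VUE patient 7, 1239 genes differed in this model, and lists were not tested in it without this patient.

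**Figure D2:**
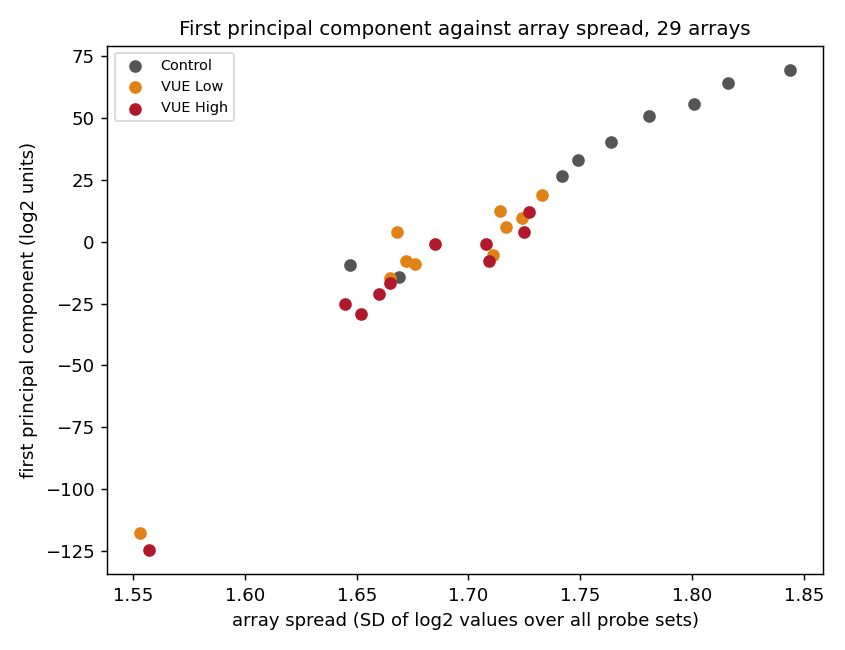
First principal component of 17116 genes (y axis, log2 units) against array spread (x axis, SD of log2 values over all probe sets), 29 arrays coloured by group. The component held 57.7% of the variance, and over 19 donors it followed array spread (Pearson's r = 0.96, Spearman's rho = 0.951, permutation p = 1e-05 for both, the smallest that the resamples can give; r = 0.969 without the 2 donors farthest from the median spread, 0.948 in the patients and 0.987 in the controls). Both arrays of VUE patient 7 lay apart from the others at a spread of 1.56 and 1.55. Both axes are computed from the values of the same arrays, so their relation does not tell which follows from the other.

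**Figure D3:**
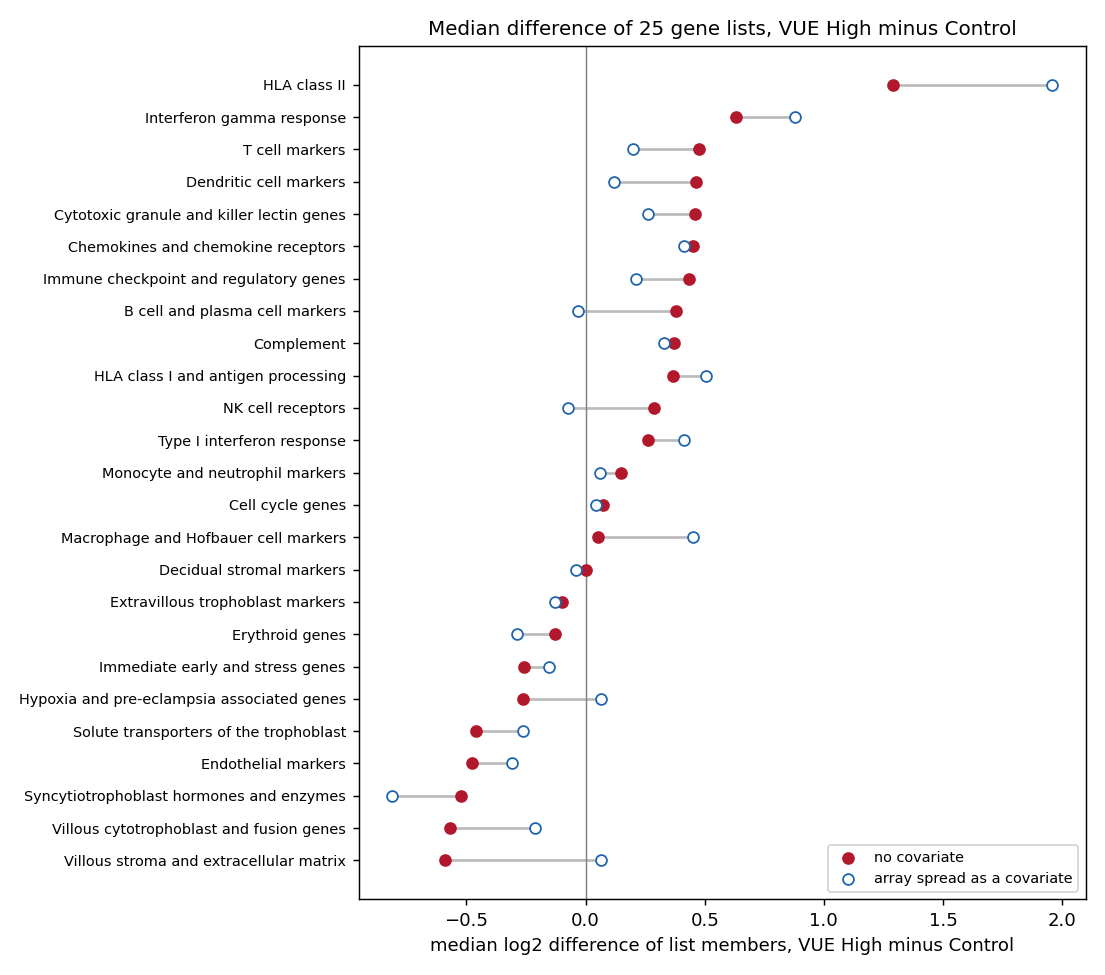
Median log2 difference between VUE High and control arrays (x axis) for the measured members of 25 gene lists (y axis). Filled points come from the model without a covariate and open points from the model with array spread. The median of HLA class II moved from 1.29 to 1.96 and that of villous stroma from -0.59 to 0.07.

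The comparison of Low arrays with controls asked how the second array of the same patients differed. CXCL10 rose by 3.22 ± 0.45 (SE; limma, adjusted p = 0.000663), from 5.52 ± 0.63 (SD, n = 9) to 8.73 ± 1.38 (SD, n = 10), and CXCL9 by 2.95 ± 0.59 (adjusted p = 0.00452). The next largest rises were SLAMF7 at 2.62, HLA-DPA1 at 1.87, GALT at 1.64, IGLC1 at 1.49, REXO1L1P at 1.48 and ANKRD22 at 1.45. SOX7 fell by 2.35 ± 0.33 (adjusted p = 0.000663), followed by APOLD1 at -2.20, the pattern recognition gene PTX3 at -2.19, DKK1 at -2.17, NEXN at -2.16, DNAJB4 at -2.10, ZNF512B at -2.08 and LYSMD3 at -2.07. HLA class II genes rose in 6 of 13 cases, or 9 adjusted over the list alone, with a median of 0.84. T cell markers rose in 9 of 20 cases, or 10 adjusted over the list alone, with a median of 0.34, and 0 of them passed with array spread as a covariate (limma). Interferon gamma response genes rose in 5 of 19 cases; adjusted over the list alone, 6 rose and 1 fell. Cytotrophoblast genes fell in 5 of 19 cases, also adjusted over the list alone, and transporters in 6 of 16, or 10 fell and 2 rose adjusted over the list alone. Endothelial markers fell in 6 of 16 cases and 1 rose, or 7 fell and 2 rose adjusted over the list alone. With estimated correlations the adjusted p was 0.608 for HLA class II, T cell, cytotrophoblast and endothelial genes, 0.656 for interferon gamma response genes and 0.122 for transporters. Array spread and the GAPDH difference also set Low arrays apart from controls, and in the model with array spread 0 cytotrophoblast and 0 endothelial genes (limma), 1 transporter, 5 HLA class II and 3 interferon gamma response genes passed. The medians went from -0.43 to -0.09 for cytotrophoblast, from -0.27 to -0.10 for endothelial, from -0.43 to -0.25 for transporter, from 0.84 to 1.19 for HLA class II, from 0.37 to 0.46 for interferon gamma response and from 0.34 to 0.07 for T cell genes. Without VUE patient 7 the endothelial median was -0.13 and the cytotrophoblast median -0.27. The 6 endothelial falls were 3 without VUE patient 10 and 2 without control 2, 8 or 10, and the 5 cytotrophoblast falls 3 without VUE patient 1 or 8 or control 5, 2 without control 1, 2, 8 or 10 and 8 without control 9. The 6 transporter falls were 3 without VUE patient 10 or control 1, 2, 8 or 10, and the 9 T cell rises 4 without control 2 and 5 without control 8. The preset call of the interferon gamma list (adjusted p = 0.0202) was lost without VUE patient 2 or control 3 or 9 (adjusted p = 0.0589, 0.074 and 0.0749).

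Of the fixed panel, the genes that passed in Low arrays were CXCL9, CXCL10, HLA-DPA1, CD74 at 1.37 ± 0.28 (SE), HLA-E at 0.59 ± 0.20, CD3D at 0.49 ± 0.14, CD8A at 0.58 ± 0.15 and CD163 at -0.86 ± 0.28, which did not pass without VUE patient 7 (limma, adjusted p = 0.0608). The others did not pass. HLA-DRA differed by 1.02 ± 0.56, CIITA by 0.69 ± 0.26, GBP5 by 0.66 ± 0.30, HLA-B by 0.52 ± 0.23, GZMA by 0.34 ± 0.25 and GZMB by 0.30 ± 0.17. CGA differed by -0.98 ± 0.36, CSH1 by -0.63 ± 0.42, IDO1 by -0.30 ± 0.22, FLT1 by -0.16 ± 0.17, LYVE1 by 0.14 ± 0.35 and CD274 by 0.01 ± 0.14. Other probe sets had the opposite sign for CD163 (0.19), LYVE1 (-0.19), CD274 (-0.33), FLT1 (0.23), IGLC1 (-0.01) and DNAJB4 (0.02), and those of GALT went down to 0.03. In total 2794 genes differed between Low and control arrays, 1142 higher and 1652 lower, and 376 of them by at least 1. The balance turned with array weights (4270 higher and 3036 lower), without control 3 (3065 and 2318), without control 9 (2868 and 2376) and with array spread as a covariate (145 and 115). With array spread as a covariate 260 differed, 161 of them among the 2794 in the same direction, and 11 of the named genes no longer passed, while HLA-B and HLA-DRA passed. Of these 11, differences shrank for CD3D (0.49 to 0.16), CD8A (0.58 to 0.35), CD163 (-0.86 to -0.40), GALT (1.64 to 0.66), REXO1L1P (1.48 to 0.84), DKK1 (-2.17 to -1.52) and ZNF512B (-2.08 to -1.09). They stayed near their size or grew for SLAMF7 (2.62 to 2.57), IGLC1 (1.49 to 1.70), ANKRD22 (1.45 to 1.62) and PTX3 (-2.19 to -2.08). The count was 1380 without control 2, 1417 without control 8, 1557 without control 10, 1563 without control 1, 1805 without control 5, 1855 without VUE patient 6, 5244 without control 9 and 5383 without control 3.

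With the High and Low values of each patient averaged, the comparison of VUE with controls asked about the disease as a whole. CXCL10 rose by 3.86 ± 0.36 (SE; limma, adjusted p = 6.55e-06), CXCL9 by 3.67 ± 0.45, HLA-DPA1 by 2.44 ± 0.46, CD74 by 1.74 ± 0.23, HLA-DRA by 1.53 ± 0.50 and CIITA by 0.99 ± 0.22. GBP5 rose by 0.80 ± 0.23, CD8A by 0.75 ± 0.12, GZMA by 0.74 ± 0.21, CD3D by 0.68 ± 0.13, HLA-B and HLA-E by 0.69 ± 0.21 and 0.69 ± 0.20, and GZMB by 0.51 ± 0.17. CGA fell by 1.14 ± 0.31 and CD163 by 0.84 ± 0.26. CSH1 at -0.82 ± 0.44, FLT1 at -0.28 ± 0.17, IDO1 at -0.24 ± 0.21, LYVE1 at 0.07 ± 0.35 and CD274 at 0.08 ± 0.13 did not pass. The probe sets of CD163 ranged from -0.84 to 0.21, of FLT1 from -1.35 to 0.19, of LYVE1 from -0.27 to 0.07 and of CD274 from -0.27 to 0.08. CGA, CD163, GZMB and GBP5 no longer passed with array spread as a covariate (adjusted p = 0.318, 0.554, 0.0718 and 0.0746). The difference shrank for CGA (to -0.61) and CD163 (to -0.32) and grew for GZMB (to 0.64) and GBP5 (to 0.91). HLA class II genes rose in 11 of 13 cases, or all 13 adjusted over the list alone (adjusted p = 0.356 with an estimated correlation). T cell markers rose in 12 of 20 cases, or 16 adjusted over the list alone (adjusted p = 0.356 with an estimated correlation). In the model with array spread 11 class II genes and 5 T cell markers passed, the medians went from 1.01 to 1.58 and from 0.40 to 0.13, and the adjusted p was 0.0354 and 0.134 with an estimated correlation. In total 5611 genes differed, 3015 higher and 2596 lower, a balance that turned among others with a stricter filter (1609 and 2032) and array median centring (2528 and 2755), and 722 with array spread as a covariate, 495 of these among the 5611 in the same direction. The count was 3346 without control 8, 3373 without control 2 and 3740 without control 10.

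The comparison of High with Low arrays within patients asked whether both arrays of a patient differ, and equally whether their differences from the controls do. In this comparison 38 genes differed, 6 higher and 32 lower on High arrays. With any 1 of patients 2 to 9 left out, 0 genes were called higher (limma). With all arrays in 1 fit and the donor as a random block, 17 were higher and 24 lower. With the GAPDH difference as a covariate 27 were higher and 42 lower. Array spread differed as well, by a mean of -0.00993 ± 0.0113 (SD, n = 10; exact permutation test, p = 0.0234, adjusted p = 0.0301), and was higher on the High array in 2 of 10 patients. CHI3L1, a glycoprotein secreted by macrophages, was 1.10 ± 0.20 higher (SE; limma, adjusted p = 0.0466), in 10 of 10 patients, at 8.63 ± 1.00 against 7.53 ± 1.13 (SD, n = 10), though its other probe sets went down to 0.03. The lysosomal lipase gene LIPA was 0.51 ± 0.09 higher, the amino acid transporter gene SLC7A7 0.44 ± 0.08, FRRS1L 0.39 ± 0.07, CD3D 0.39 ± 0.07 and JAML, an adhesion molecule of leukocytes, 0.37 ± 0.07. Other probe sets of LIPA and FRRS1L lay near 0, at 0.04 and 0.02. RCAN1, a regulator of calcineurin, was lower by -0.61 ± 0.06 (adjusted p = 0.000591), in 10 of 10 patients. The other large falls were ISM1 at -0.79, KL, which encodes Klotho, at -0.74, the alarmin gene IL33 at -0.72, MCCC2 at -0.70, CYYR1 at -0.66, ADRB1 at -0.62 and SCN7A at -0.61, although the other 2 probe sets of MCCC2 had the opposite sign. Those of ISM1 and ADRB1 reached -0.03 and -0.01. KDR, the main receptor for vascular endothelial growth factor, fell by 0.43 ± 0.08 (adjusted p = 0.0391) and ESAM differed by -0.38 ± 0.08 without passing (adjusted p = 0.0727). Without patient 7, KDR, IL33, CYYR1 and SCN7A did not pass (limma, adjusted p = 0.0684, 0.0684, 0.0639 and 0.0627).

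Few members of the immune lists passed the threshold over all genes between High and Low arrays. Adjusted over the list alone, 12 of 13 HLA class II genes, 9 of 20 T cell markers, 5 of 14 cytotoxic genes and 6 of 19 interferon gamma response genes were higher, and 8 of 16 endothelial markers were lower. Over all genes 1 T cell marker, CD3D, was higher, with LCK at 0.27 ± 0.07 not passing, and 1 endothelial marker was lower. Camera with a preset correlation called 17 of 25 lists, 12 higher and 5 lower. With estimated correlations 0 were called (limma), with adjusted p = 0.0775 for T cell and cytotoxic genes, adjusted p = 0.0837 for endothelial, adjusted p = 0.105 for HLA class II and adjusted p = 0.171 for interferon gamma response genes. CXCL9 at 1.44 ± 0.40, CXCL10 at 1.28 ± 0.29, HLA-DPA1 at 1.13 ± 0.27, HLA-DRA at 1.03 ± 0.27, GZMA at 0.80 ± 0.20, CD74 at 0.74 ± 0.17 and CIITA at 0.61 ± 0.13 did not pass. Nor did GZMB at 0.42 ± 0.14, HLA-B at 0.35 ± 0.12, CD8A at 0.34 ± 0.10, GBP5 at 0.28 ± 0.16, HLA-E at 0.20 ± 0.07, CD274 at 0.15 ± 0.05, IDO1 at 0.12 ± 0.10, CD163 at 0.03 ± 0.13, LYVE1 at -0.15 ± 0.13, FLT1 at -0.23 ± 0.09 (with a probe set at 0.11), CGA at -0.32 ± 0.26 or CSH1 at -0.37 ± 0.15. The count of 38 fell to 0 with array spread as a covariate (limma; 1338 genes at an unadjusted p under 0.05, against 2329 without it), while differences of several named genes moved little, such as CHI3L1 (1.10 to 1.01), RCAN1 (-0.61 to -0.57) and KL (-0.74 to -0.76), and others more, such as IL33 (-0.72 to -0.47) and CD3D (0.39 to 0.28). It was also 0 without the patient as a replicate block, and 39 without patient 1, 20 without patient 10, 15 without patient 5, 12 without patient 4, 7 without patient 7, 4 without patient 3, and 1 without patient 2, 6, 8 or 9.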

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

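The tests of array spread as a cause and of a lower trophoblast share were chosen after the results were seen; the criteria for array spread were also rewritten once after its values were known. Under the first wording, in which the median had to fall below 50% of its value for array spread to count as the cause, the T cell markers would have stayed undecided. The criterion for the trophoblast share was changed 2 times after its values were known: with the endothelial and stromal medians as the criterion, this explanation was argued against without array spread (-0.477 and -0.59) and stayed open with it (-0.308 and 0.0667). The regroupings of samples and the relation between immune and trophoblast genes within patients were set beforehand. The regroupings with array spread, however, used a covariate chosen after the data were seen.

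The count of 6389 genes in High against control was met or passed by 2 of 100 regroupings of the same arrays, the real one included. These were drawn from 92378 possible regroupings, so chance is unlikely but is not excluded. The highest other regrouping gave 7369 genes, more than the real groups, and its groups differed in array spread by -0.0955, against -0.0838 for the real groups, which points to a structure of the samples. For Low against control (2794, highest other 0), the patient means (5611, highest other 4617) and High against Low (38, highest other 1, among regroupings that part every pair) only 1 of 100 regroupings was as large, the real one, which makes chance unlikely without excluding it. The 38 genes of High against Low were 1 without patient 2, 6, 8 or 9. With array spread as a covariate the real count of 735 was likewise reached by 1 of 100, with 2 as the highest other count. Of those other regroupings 3 differed in array spread as much as the real groups, so they say little on what the covariate leaves in groups that do. The 735 argues against array spread as the whole source only if genes follow it in a straight line, as the model assumes. Most calls ended with the covariate. Simulated arrays with no group effect and the measured spread gave 4964 calls without it and 0 with it in High against control (limma). They gave 3346 and 1 for the patient means, so array spread may account for a large part in both. The simulated genes followed spread in a straight line, so the low counts with the covariate were given by the construction. For Low against control the same simulation gave 3 calls, against 2794 measured. The spread differences were close (-0.0738 for Low, -0.0838 for High), and 1 data set was simulated per comparison, without repeats. Whether repeats would vary from 3 to 4964 is thus not known, and none of these simulated counts settles the share due to array spread. With the covariate the 2794 genes of Low fell to 260. Some calls ended though the difference held, as for SLAMF7 (2.62 to 2.57) and PTX3 (-2.19 to -2.08). Other differences shrank, such as that of CD3D (0.49 to 0.16). How large a part goes with array spread stays open there too.

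The rise of HLA class II and T cell genes in High arrays stayed with array spread as a covariate (adjusted p = 0.00506 and 0.0199 with an estimated correlation). The class II median went from 1.29 to 1.96 with a median SE of 0.249 before and 0.262 after, and the T cell median from 0.478 to 0.2 with 0.127 and 0.116, so array spread as the whole cause is argued against for both, while a part of the T cell rise may come with it. A lower share of trophoblast would raise every other cell type alike, but the HLA class II mean rose in High arrays by 2.09 ± 0.194 (SE) relative to the endothelial mean and 2.08 ± 0.185 relative to the stromal mean, and by 2.38 ± 0.222 and 2.04 ± 0.239 with array spread as a covariate (permutation p = 1e-05 for each, the smallest that the resamples can give, adjusted p = 2e-05 over 8 tests, with 10 of 10 High arrays above the control mean). These gaps combine mean differences already known (1.63 for class II, -0.461 for endothelium and -0.457 for stroma). The criterion was set after that, so the p-values add no independent support. The values argue against a lower trophoblast share as the only source of the class II rise. The T cell mean moved by 1.0 ± 0.161 relative to endothelium and 1.0 ± 0.267 relative to stroma (permutation adjusted p = 4.8e-05 and 0.00032), and by 0.63 ± 0.14 and 0.292 ± 0.186 with array spread (adjusted p = 0.000354 and 0.138). More immune cells and stronger expression per cell both stay open, and neither was tested.

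The transporters of the trophoblast were called lower with array spread as a covariate (median -0.264, adjusted p = 0.0292 with an estimated correlation). Array spread is the SD of the same values, so it may itself follow from a difference between the groups. The covariate may then remove a part of that difference, or enlarge others. With this limit, array spread stays open as an account of the lower cytotrophoblast and stromal genes. Their calls at the preset correlation ended with this covariate (adjusted p from 0.000222 to 0.058 and from 0.00856 to 0.275) as the medians shrank from -0.57 to -0.211 (median SE 0.26 and 0.193) and from -0.59 to 0.0667 (0.257 and 0.218; -0.336 without patient 7 and without the covariate), while with an estimated correlation neither list was called without it (adjusted p = 0.194 and 0.452) or with it (0.418 and 0.774). For the syncytiotrophoblast, adjusted p = 0.292 with an estimated correlation but 5.48e-07 with the preset one, and the median moved from -0.524 to -0.814 while its median SE rose from 0.316 to 0.385, so array spread and group cannot be told apart for this list. Dilution by immune cells cannot be told apart from a fall per cell either, because over 10 patients the High minus Low differences of T cell and syncytiotrophoblast genes had Pearson's r = -0.184 (permutation p = 0.622) and Spearman's rho = -0.00606 (p = 1). Villous damage in VUE, a biological explanation that the groups allow, was not tested.

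Dixon's ratio, the gap of the end value to its neighbour over the range of the group, was beyond its 95% limit in 63 of 315 groups of values, where chance gives about 1 in 20, or 16. Of these 56 were in VUE groups, and in 48 the end value was from patient 7. On High arrays the ratio was 0.49 for the array median, 0.518 for array spread and 0.669 for the GAPDH 3' to 5' difference, and on Low arrays 0.561, 0.622 and 0.612. On High arrays the mean of the list had a ratio of 0.505 for T cells, 0.667 for NK cell receptors, 0.521 for B cells, 0.612 for dendritic cells, 0.487 for chemokines and 0.535 for erythroid genes, with the end value highest, and 0.545 for cytotrophoblast, 0.65 for endothelium, 0.767 for stroma and 0.537 for transporters, with it lowest. On Low arrays it was 0.557 for NK cell receptors, 0.779 for B cells and 0.524 for dendritic cells, highest, and 0.589 for cytotrophoblast, 0.523 for endothelium, 0.683 for stroma and 0.622 for transporters, lowest. In controls it was 0.517 for chemokines and 0.581 for endothelium, highest, and 0.597 for HLA class II and 0.521 for transporters, lowest.

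Among single genes on High arrays the ratio was 0.522 for IDO1 and 0.594 for FRRS1L with the end value highest. With it lowest, the ratio was 0.561 for HLA-E, 0.608 for CD163, 0.627 for TFAP2A, 0.598 for SOX17, 0.501 for ACTA2, 0.503 for MYH11, 0.491 for SLC2A1, 0.48 for KL, 0.513 for CYYR1, 0.637 for ADRB1, 0.511 for SCN7A and 0.652 for KDR. On Low arrays the end value was highest for CD3D (0.552), GZMA (0.47), GBP5 (0.868), IGKC (0.538), FOLR2 (0.6), LIPA (0.478), SLC7A7 (0.49) and FRRS1L (0.598). It was lowest for DNAJB4 (0.611), HLA-E (0.56), LYVE1 (0.672), IFI6 (0.541), GCM1 (0.649), TFAP2A (0.721), ESAM (0.654), MYH11 (0.512), SLC2A1 (0.661), SCN7A (0.642) and KDR (0.534). In controls it was lowest for ANKRD22 (0.552) and highest for POU2AF1 (0.586) and GALT (0.554).

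The differences of High and of Low arrays from controls differed from each other for 38 genes, by the test of High against Low itself. Of 9632 probe sets with no gene symbol or several, which no comparison of genes used, 3045 differed between High and control arrays, 2203 higher and 842 lower (limma).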

How the results depend on the processing

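Array spread and the GAPDH difference as covariates, array spread without patient 7, and members of gene lists counted without each donor were chosen after the data were seen, and the other alternatives before. For High against control the 6389 genes were 4019 with a stricter filter, which tests fewer genes, 14153 when each probe set was counted, 788 with a log2 change of at least 1, 735 with array spread as a covariate, 1407 with the GAPDH difference and 1239 with array spread and without patient 7. For Low against control the 2794 genes were 6108 by probe set, 1794 after quantile normalization, 7306 with array weights, 376 with a change of at least 1, 260 with array spread, 495 with the GAPDH difference and 643 with array spread and without patient 7. For the patient means the 5611 genes were 3641 with the stricter filter, 12572 by probe set, 9635 with array weights, 551 with a change of at least 1, 722 with array spread, 1156 with the GAPDH difference and 1295 with array spread and without patient 7. For High against Low the 38 genes, 15.8% of them higher, were 0 with the mean of probe sets (limma), 1 by probe set, 4 after quantile normalization, of which 0 were higher, 1 with a change of at least 1, 0 with array spread (limma; 1338 genes at an unadjusted p under 0.05), 69 with the GAPDH difference and 1 with array spread and without patient 7. Except where the construction shows it, the cause was not tested. Genes lower outnumbered those higher, against 54.8% higher for High and 53.7% for the patient means, with the stricter filter (44% and 44.2%), median centring (48.9% and 47.9%), the replicate block (46.2% and 39.7%), a change of at least 1 (13.6% and 11.4%), the GAPDH difference (41.2% and 42.4%) and array spread without patient 7 (45.4% and 46.6%), and for the means with quantile normalization (48.3%). They also did for High without VUE patient 7 or control 1, 2, 8 or 10 (47.8% to 49.6%), and for the means without VUE patient 4, 6, 7, 8 or 10 or control 1, 2, 5, 8 or 10 (43.3% to 49.6%). For Low, 40.9% higher turned to 58.4% with array weights, 55.8% with array spread, and 56.9% and 54.7% without control 3 and 9. No filter, median centring, no variance trend and all arrays with the donor as a random block, where run, moved no total count by over 1.5 times. The 6 higher genes of High against Low were 3 with median centring, 2 with no variance trend and 17 with the donor as a random block.

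Patients and controls share 9 numbers, and they were treated as unpaired. Deviations of same-numbered arrays correlated over 0.1 in 3 of 9 pairs for High and 1 of 9 for Low, and 1 sample correlated best with its own number in each. These values give no sign of a shared donor, but they cannot tell whether controls were matched to patients on other traits. With the number as a replicate block the counts were 4137, 1033 and 2816 for High, Low and patient means against control. Without the patient as a block, High against Low gave 0 genes (limma).

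Leaving out each donor gave 4350 to 8423 genes for High against control, 1380 to 5383 for Low against control, 3346 to 8300 for the patient means and 1 to 39 for High against Low. Counts that moved by over 1.5 times were, for Low, 1855 without VUE patient 6, 1563, 1380, 5383, 1805, 1417, 5244 and 1557 without controls 1, 2, 3, 5, 8, 9 and 10, for the patient means 3373, 3346 and 3740 without controls 2, 8 and 10, and for High against Low 1 without patient 2, 6, 8 or 9, 4 without 3, 12 without 4, 15 without 5, 7 without 7 and 20 without 10. HLA-DQA1 in High against control lost its call without VUE patient 1 (2.10), 3 (2.11), 5 (2.16), 6 (2.20), 8 (2.37) or 10 (2.29), or control 2 (2.17), 4 (2.23), 5 (2.14) or 9 (2.13), and CD163 without control 2 (-0.69), while CSH1 gained one without control 2 (-1.28) and FLT1 without control 4 (-0.46). Over all donors left out, calls of named genes were lost 45 times and gained 9 times for Low against control. They were lost 109 times and gained 1 time for High against Low, and lost 3 times for the patient means. In High against control, no donor left out moved the count of genes called or the median of HLA class II, T cell, cytotoxic, chemokine, checkpoint, dendritic or cytotrophoblast genes by over 1.5 times. The number of gene lists called ran from 14 to 16, 12 to 15, 14 to 16 and 14 to 19 in the 4 comparisons.

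With an estimated correlation 0 of 25 lists were called in each comparison (limma's camera), against 14, 14, 14 and 17. With array spread as a covariate as well, 10, 0, 1 and 0 were called. With array spread alone the set test of macrophages turned from lower to higher (medians 0.451, 0.217 and 0.333 for High, Low and patient means, against 0.0537, -0.000141 and 0.0685). The median of stroma turned positive (0.0667, 0.233 and 0.115) and that of B cells negative (-0.0333, -0.0655 and -0.0534). Among lists not called in either model, medians of NK cell receptors (0.286 to -0.0724 for High) and hypoxia genes (-0.261 to 0.0667 for High), among others, also changed sign. The 38 genes of High against Low rest on small differences between few pairs, and signal over background was not measured beyond the filter on dim genes.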

Other observations

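The relations within patients were set before their values were seen, and array spread as a covariate and the counts of list members without each donor were chosen after. Of the gene lists described next, that of dendritic cells alone was called between High arrays and controls (adjusted p = 0.00171). CLEC9A, LAMP3 and CLEC4C, among the 12 dendritic cell markers fixed, were not tested. Of 9 dendritic cell markers 6 rose, or 7 adjusted over the list alone, among them CD83, a marker of mature dendritic cells, by 1.22 ± 0.17 (SE) and CD1C by 0.65 ± 0.13, and the camera call was lost at adjusted p = 0.295 with an estimated correlation. In the model with array spread 1 member passed, the median went from 0.463 to 0.119 (adjusted p = 0.0657 with an estimated correlation), CD83 was at 1.19 (adjusted p = 0.00264) and CD1C at 0.38 (adjusted p = 0.107). Of 16 complement genes 7 rose and 2 fell, or 9 rose and 2 fell adjusted over the list alone, and the list was not called (adjusted p = 0.194). Given array spread it was called, with 4 members higher and 0 lower (limma; adjusted p = 0.044 with an estimated correlation). The receptor gene C3AR1 rose by 0.60 ± 0.11, while CD55 and CD59, which protect cells from complement, fell by 1.00 ± 0.21 and 0.77 ± 0.19, and no longer passed given array spread (-0.39 and -0.30, adjusted p = 0.129 and 0.364). Of 16 monocyte and neutrophil markers 3 rose and 1 fell, by either adjustment including that over the list alone, with FCN1 at 0.70 ± 0.14 and FCGR3B at 0.83 ± 0.17, and of 6 NK cell receptors 3 rose, also adjusted over the list alone. Neither list was called (adjusted p = 0.348 and 0.233), and given array spread 3 monocyte and neutrophil markers and 0 NK cell receptors passed (limma), the NK median going from 0.286 to -0.0724. Without control 8, 4 complement genes and 1 NK cell receptor rose, and without VUE patient 3, 5 monocyte and neutrophil markers.

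Of 10 erythroid genes 1 fell, also adjusted over the list alone (list adjusted p = 0.382). HBB, the beta chain of adult hemoglobin, fell by 1.20 ± 0.23. Of 18 cell cycle genes 1 rose and 5 fell, also adjusted over the list alone, with a median of 0.07 but a mean of -0.08 (adjusted p = 0.438). MKI67 rose by 0.44 ± 0.13 and CCNA2 fell by 0.82 ± 0.22, which was -0.26 given array spread (adjusted p = 0.509). Of 19 hypoxia and pre-eclampsia genes 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.11). Of 14 extravillous trophoblast markers 1 rose and 2 fell, or 2 fell adjusted over the list alone (adjusted p = 0.265), and of 10 decidual markers 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.73; median 0.004, mean -0.304). The extravillous median of -0.0975 was 0.0492 after quantile normalization, and the decidual median of 0.00359 was -0.0432 after median centring. The 3 decidual rises were 1 without VUE patient 1, 6, 7, 8 or 10 or control 1, 2, 4, 5, 8 or 10. The 5 cell cycle falls were 3 without VUE patient 1 or 8 or control 1, 2 or 8, and the 4 hypoxia falls 2 without VUE patient 4 or 10 or control 2, 5, 8 or 10. Given array spread 1 erythroid gene was lower, 3 cell cycle genes higher, 1 hypoxia gene lower, and 0 extravillous and 0 decidual markers passed (limma).

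Within the 10 patients the mean T cell value was 0.182 ± 0.154 (SD) higher on High arrays, in 9 of 10 patients, and that of HLA class II 0.668 ± 0.676, in 8 of 10. A hypothesis that patients with a larger T cell difference also have a larger HLA class II difference was met by Pearson's r = 0.808 (permutation p = 0.00759, adjusted p = 0.0304 over 4 relations) and Spearman's rho = 0.818 (p = 0.0058, adjusted p = 0.0232). Without the 2 patients farthest from the median r was 0.752, and given the difference in array spread it was 0.953, so both may vary with the same immune infiltrate.

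A larger T cell difference did not go with a larger fall of endothelial markers beyond chance (r = -0.337, permutation p = 0.337, adjusted p = 0.449; rho = -0.321, p = 0.37; r = 0.106 without the 2 farthest patients). Its relation to the difference in array spread was also left undecided (r = -0.473, permutation p = 0.166, adjusted p = 0.332; rho = -0.491, p = 0.155; r = -0.101 without the 2 farthest patients). Endothelial markers were lower on High arrays by a mean of -0.202 ± 0.156 (SD), higher in 1 of 10 patients.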
